A study of Malus domestica with 48 samples.

How the data were processed

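RNA was measured in 48 samples of apple (Malus domestica) from 2 cultivars, Golden Delicious and Granny Smith, at 8 stages with 3 biological replicates each, which gave 16 groups. The stages on the tree were flower, fruitlet, green fruit of 3 cm, mature green fruit of 6 to 8 cm, breaker and harvest. The last 2 stages were fruit after harvest, either left as a control or treated overnight with 1 ppm of 1-methylcyclopropene (1-MCP), a gas that blocks the ethylene receptors. Tissue was flower at the first stage and fruit cortex at the others. Per the labels, RNA was amplified, labelled with Cy5 and hybridised to a custom oligonucleotide array named iRIPE, with 1 sample per hybridised area.

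Per the file headers, the scans were read at 635 nm with GenePix Pro 7.1.26, and each spot carries a median foreground and a median local background intensity with no normalisation. Each scan held a whole chip with 2 sectors, and the headers name 2 samples per scan. The first-named sample was taken to be in sector 1 and the second in sector 2. This order was checked against the authors' value table: values were ranked within an array and each target's mean rank over arrays was taken off, and on 42 of 48 arrays the own sector then correlated with the sample's column over targets at r of 0.855 to 0.970. The other 6 arrays are named below. For 4 pairs of samples the deposited scan was the same file, and each sample then took its own sector. The scans came from 8 chips that were hybridised up to 4 times, in 27 hybridisations. Of these, 21 held 2 samples of the series and 6 held 1. Sectors that held other samples were never used as samples.

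The authors also deposited a table of log2 values for 3404 targets, with 2 missing cells and column medians of 8.50 to 8.61. The submitters' processing notes name limma without a version, and state neither the background correction, the summary over probes nor the normalisation. Over the 42 arrays the authors' values correlated at r of 0.983 to 0.988 with the normalised values described next, with a median slope of 1.14. The authors' table served as an alternative source of values.

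Each sector held 7693 probes for 3420 targets, with 4 to 23 spots per target (median 9), and 2569 spots of negative controls. Foreground intensities were corrected for local background with limma's normexp method and an offset of 50 on all spots of a sector, then taken to log2. Control spots were dropped, arrays were quantile normalised over target spots, and spots were averaged per probe and probes per target. A target was tested where its intensity lay above the 95th percentile of the negative controls on at least 1 of the 48 arrays, which left 1101 of 3420 targets. On single arrays 4.33% to 24.4% of targets lay above that level. Saturated spots (most of the pixels at the limit) were kept: 56 targets had at least 1, and 5 had most of their spots saturated on all arrays of a group. No depth exists for arrays, and the number of arrays limits the precision.

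The files hold target identifiers without gene names, and the reference given (gene models of assembly GDT2T_hap1) matched 0 of the identifiers. The 22 gene lists fixed for ethylene, auxin, cell wall, aroma and other functions therefore could not be matched, and no list was tested. The targets that a rule fixed beforehand would have named are counted. The rule took, for the 4 comparisons of control with harvest and of 1-MCP with control, the 10 largest rises and 10 largest falls with adjusted p under 0.05, no overlap between the groups, and a group mean above the median of all targets. It took 5 of each for other comparisons, and it named targets only where a gene name was given. The 4 identifiers printed are the 2 first rises and the 2 first falls of its ranking for 1-MCP in Golden Delicious, and were chosen after their values were seen. Sets of targets taken from the data themselves replaced the gene lists, and were also chosen after the values were seen.

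One linear model with 16 group means was fitted across all targets with limma 3.58.1 in R 4.3.3, with data.table for reading (version 1.17.8), and 18 comparisons were taken from it. A target was called at an adjusted p (Benjamini-Hochberg, 2-sided) under 0.05 from limma's moderated test. In 5 comparisons of successive stages on the tree the mean of both cultivars was compared, and a moderated F test over 5 contrasts tested whether the cultivars differed by stage. Where a target lay under the negative controls on all arrays of 1 side, its fold was computed against a floor and is given as "at least". On each array the floor was the lowest normalised value among targets above the 95th percentile of the negative controls. The target's own value was used where it was higher. Sets were the targets called with at least a 2-fold change in one comparison, tested in a comparison of other arrays. Set tests used camera with a preset correlation, camera with an estimated correlation and fry, with adjustment over 56 tests (8 in the fit with 2 arrays per group), and an exact 2-sided permutation test of the set mean, which cannot give a p under 0.1 with 3 against 3 arrays. Loading and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

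Whether replicate numbers pair the arrays was checked by correlating the residuals of arrays with the same number. All 3 same-number pairs lay above 0.1 in the Golden Delicious comparisons after harvest: r was 0.20, 0.24 and 0.25 for 1-MCP against control, 0.21, 0.24 and 0.38 for control against harvest, and 0.16, 0.25 and 0.35 for 1-MCP against harvest. With the replicate block (replicate number as a factor) these counts were 131, 148 and 165 targets. That factor is a shift per number common to all 16 groups and both cultivars. It does not pair arrays within these groups, so these counts cannot show whether pairing matters. In no other comparison of 3 against 3 arrays were all 3 pairs above 0.1, as in control against harvest in Granny Smith (-0.30, -0.44 and -0.36), so the numbers were not read as pairs there. Residuals of the 21 pairs of arrays in one hybridisation correlated at a mean r of 0.39, against 0.15 for other pairs on one chip and -0.026 for pairs on different chips.

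The pipeline was tested on simulated data with known folds and the residual spread of each target on these arrays. The noise was drawn independently for each target and array, without any likeness of arrays in one hybridisation or chip. The shares below therefore do not cover that likeness, which matters most where both cultivars are compared or averaged. For 3 against 3 arrays it called 70.2% of 1.5-fold, 94.5% of 2-fold and 100% of 4-fold changes, with 5.16% of calls false. For the mean of both cultivars the shares were 83.3%, 98.1% and 100%, with 9.77% of calls false, above the nominal 5%. For the F test they were 30.5%, 77.8% and 100%, with 3.33% false. The simulated folds were set on the whole foreground intensity, non-specific signal included. After background correction 2-fold changes were estimated at a median of 2.70-fold and 4-fold changes at 6.13-fold in the 3 against 3 case. The log2 changes given are thus wider than those of the foreground. The simulation cannot tell which of the 2 scales is nearer to the RNA.

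Alternatives fixed before the data were examined were median scaling, cyclic loess, no background correction, a filter at the 25th percentile, a fit of the groups compared alone, the replicate block, a variance trend with a robust prior, the median of spots, the authors' table, chip as a random block, and leaving out each array of the groups compared in turn. Alternatives chosen after seeing the data were chip or sector or both as factors, hybridisation as a random block, leaving out 6 arrays or the failed array, leaving out 1 array in each of 6 groups, other assignments of the green sectors, leaving out the green and mature green stages, and all 3420 targets without a filter. The fit with 2 arrays per group left out, in harvest, control and 1-MCP fruit, 1 array per group so that the rest share no hybridisation or chip with the same stage of the other cultivar: control 1, 1-MCP 3 and harvest 2 of Golden Delicious and control 2, 1-MCP 1 and harvest 2 of Granny Smith. The 6 arrays that do not match are those whose own sector did not match the authors' column: Golden Delicious flower 3 (r on centred ranks = 0.707), mature green 3 (0.227), green 2 (0.625) and green 3 (0.607), and Granny Smith green 3 (0.617) and 1-MCP 2 (0.543). Golden Delicious mature green 3 is called the failed array here: 4.33% of its targets lay above the negative controls, and it correlated with its 2 replicates at -0.196 and -0.222, with target means taken off. Without any centring its normalised values correlated with the authors' column at 0.630. All 48 arrays stayed in the values reported.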

Results

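Expression was measured on 48 arrays of apple flower and fruit cortex, 3 per group, in Golden Delicious and Granny Smith from flower to fruit after harvest. The median target intensity of an array was 818 to 1341, against a median of 626 to 1304 for its negative controls, and the local background was 38 to 102. Signal over background was thus narrow for most targets, and 1101 of 3420 targets rose above the negative controls on at least 1 array and were tested. With each target's mean over all arrays taken off, replicates correlated over targets at a median r of 0.884, with a range of -0.222 to 0.982. The lowest values came from Golden Delicious mature green 3, which stood apart from its stage. Component 1 of the arrays held 45.0% of the variance and ran from fruitlet to the control fruit after harvest, and component 2 held 17.3% and set flowers apart from green fruit. On component 1 the 1-MCP arrays of both cultivars lay on the side of younger fruit from their controls, at 16.7 to 18.7 against 21.5 to 22.7 in Golden Delicious and 10.9 to 13 against 20.3 to 21.1 in Granny Smith.

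**Figure D1:**
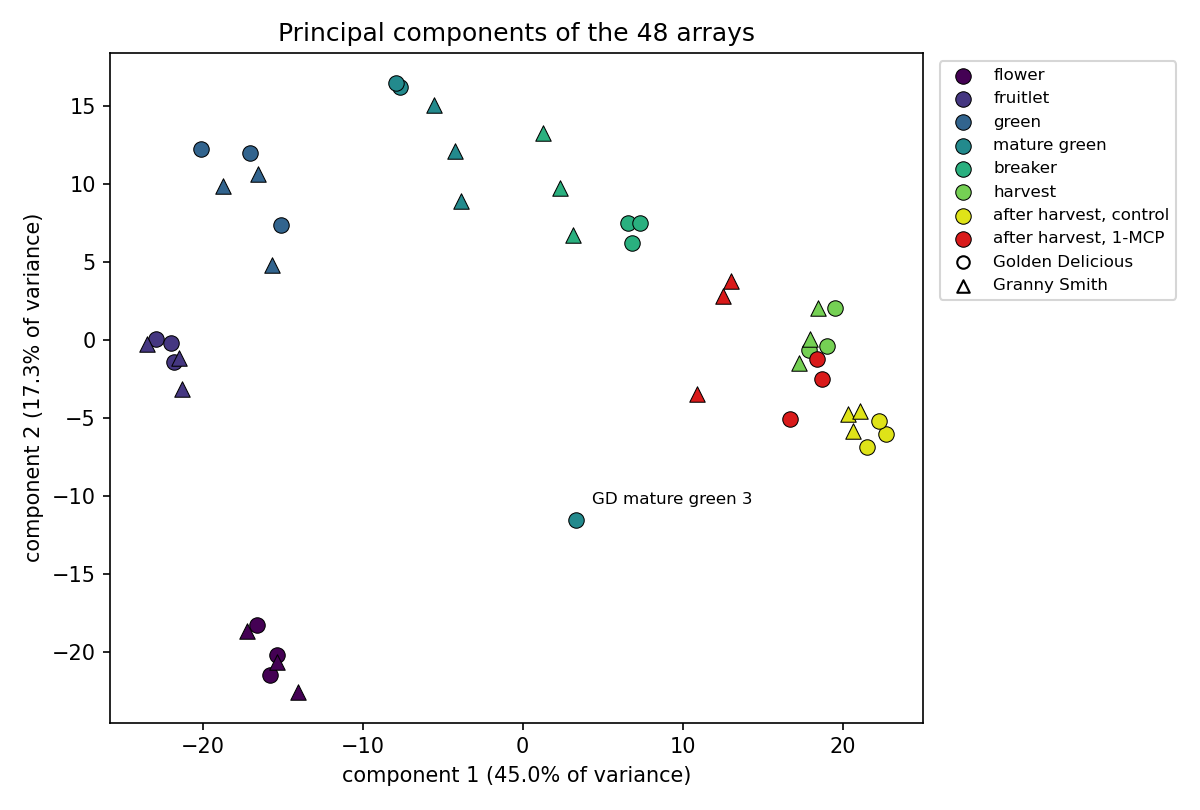
Principal components 1 and 2 of the 48 arrays over the 1101 targets, with the share of variance on each axis, colour for stage and symbol for cultivar. Arrays run along component 1 (45.0%) from fruitlet to control fruit after harvest, and Golden Delicious mature green 3 lies away from its replicates.

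The comparison of 1-MCP with control fruit after harvest asked which targets depend on ethylene perception, the subject the series title names. In Golden Delicious 78 targets were lower and 57 higher after 1-MCP, of which 43 fell and 21 rose at least 2-fold. In Granny Smith 57 were lower and 58 higher, of which 28 fell and 41 rose at least 2-fold. The median absolute log2 change of the called targets was 0.98 in Golden Delicious and 1.33 in Granny Smith, and 0.69 and 0.84 without background correction.

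Ranked by log2 change, the first fall was the same target in both cultivars, though its level after 1-MCP lay under the negative controls, so that its rank is not a measured one. MDP0000326734 was 7.53 ± 0.092 (log2 intensity, SD, n = 3) after 1-MCP and 13.74 ± 0.094 in control fruit of Golden Delicious, at least 11.1-fold lower (log2 change -6.21 ± 0.17, SE, limma adjusted p = 5.76e-27). In Granny Smith it was 7.50 ± 0.29 after 1-MCP and 12.20 ± 0.22 in the control, at least 4.91-fold lower (log2 change -4.69 ± 0.17, limma adjusted p = 1.06e-22). It lay above the negative controls on all 3 arrays of harvest (11.41 ± 0.17 in Golden Delicious, 11.66 ± 0.24 in Granny Smith) and of control fruit, and on no array of the other 6 stages. MDP0000251256 fell from 11.99 ± 0.12 to 8.18 ± 0.22 in Golden Delicious, at least 3.29-fold (limma adjusted p = 3.11e-15). In Granny Smith MDP0000251256 fell by 1.51 on the log2 scale (limma adjusted p = 1.34e-05), with both means under the negative controls, so that no fold is given.

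Among the targets higher after 1-MCP in Golden Delicious, MDP0000205389 went from 12.88 ± 0.39 in the control to 15.61 ± 0.28, 6.63-fold higher (limma adjusted p = 8.99e-08). MDP0000240094 went from 7.53 ± 0.19 to 10.46 ± 0.11, at least 1.35-fold higher (limma adjusted p = 2.18e-05). In Granny Smith neither passed the test: the log2 change was 0.72 for MDP0000205389 (limma adjusted p = 0.237) and 1.30 for MDP0000240094 (limma adjusted p = 0.0910). The test of the difference between cultivars was passed by MDP0000205389 (limma adjusted p = 6.88e-03) and not by MDP0000240094 (limma adjusted p = 0.288). In harvest fruit of Golden Delicious MDP0000205389 was at 15.04 ± 0.27 and MDP0000240094 at 10.44 ± 0.16, and their differences from the 1-MCP fruit did not pass the test (limma adjusted p = 0.273 and 0.971). For MDP0000205389 the scanner limits this comparison: in Granny Smith it stood at 15.02 ± 0.20 in the control and 15.74 ± 0.090 after 1-MCP, where 2 to 3 of its 4 spots were saturated on each array. In Golden Delicious 0 to 4 of the 4 spots were saturated after 1-MCP, with most of them on 1 of 3 arrays. Its 6.63-fold rise and the smaller rise in Granny Smith may thus be understated. The files do not pair these identifiers with gene names.

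**Figure D2:**
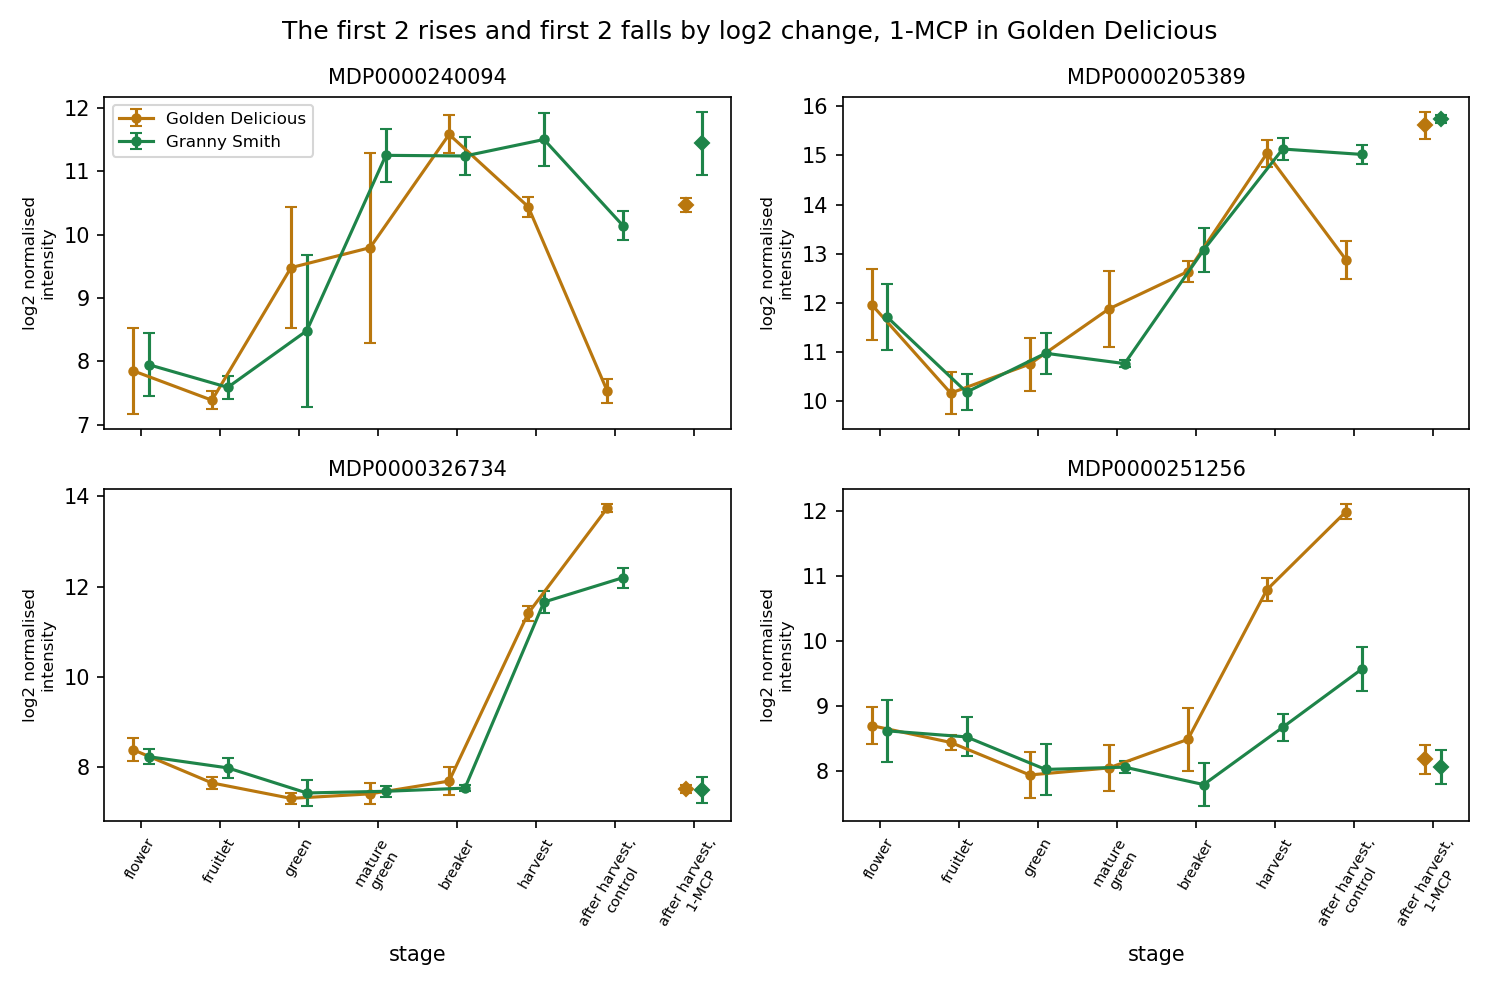
Mean log2 normalised intensity (SD, 3 arrays per point) by stage in the 2 cultivars for the first 2 rises and the first 2 falls by log2 change under 1-MCP in Golden Delicious, of which 3 have one side under the negative controls. Diamonds are 1-MCP fruit, and in both cultivars MDP0000326734 is high at harvest and in control fruit after harvest and low after 1-MCP.

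The cultivars shared 37 targets that were lower after 1-MCP, against 4.04 expected by chance (Fisher's exact test, one-sided, p = 9.93e-33), and 19 that were higher, against 3.00 expected (p = 3.60e-12, Fisher's exact test). Of the targets called in both cultivars 1 moved in opposite directions. The p values treat targets as independent, and the cultivars shared hybridisations: 1 held a control array of each and 2 held a 1-MCP array of each. Both lists also rest on a common variance per target, so targets of low variance tend to be called in both cultivars. The expected numbers leave this out, here and in the overlaps of comparisons with harvest fruit below. It would add calls in opposite directions as well. Across the 1101 targets, which are not independent replicates, the log2 changes of the cultivars correlated at a Pearson r of 0.642 and a Spearman rho of 0.508. In a fit with 2 arrays per group, where the cultivars shared no hybridisation or chip within a treatment, 20 lower (1.76 expected) and 5 higher targets (0.752 expected) were shared, and r was 0.474 (Pearson) and rho 0.146 (Spearman). The 1-MCP effect itself differed between the cultivars for 42 targets, with the change more negative in Golden Delicious for 32 and more positive for 10. That count was 84 without Golden Delicious mature green 3, a failed array in no group compared here, and 83 with hybridisation as a random block.

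**Figure D3:**
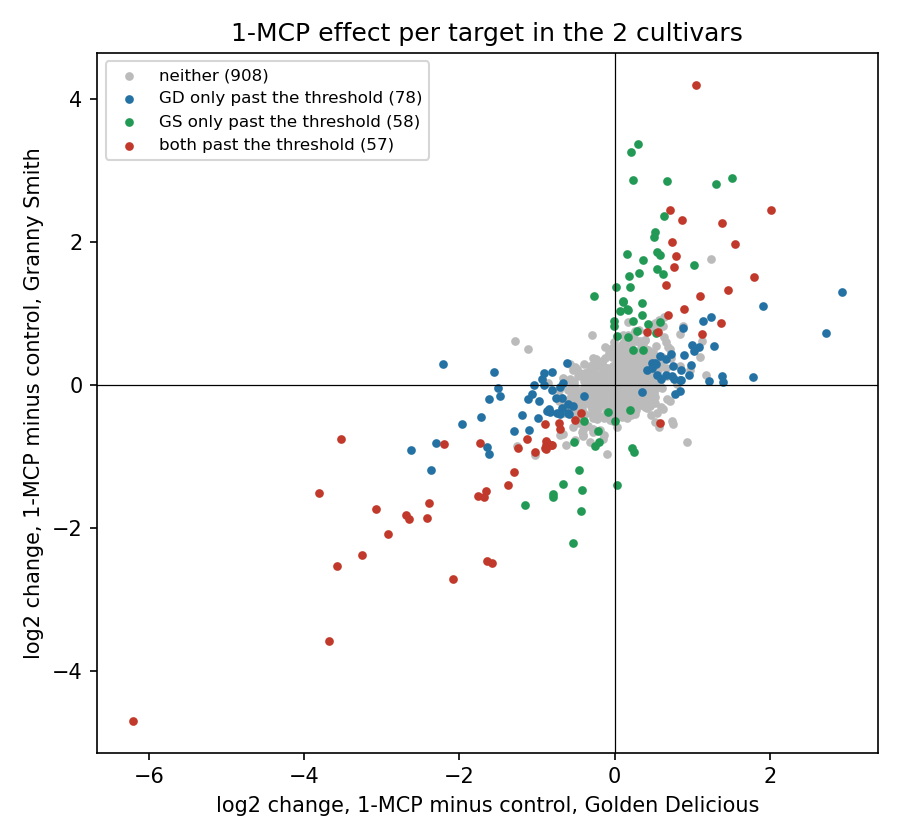
Log2 change of each of the 1101 targets under 1-MCP against control in Golden Delicious (x) and Granny Smith (y), coloured by which cultivars passed the threshold. Of the shared targets 37 fell and 19 rose in both cultivars and 1 moved in opposite directions.

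Of the called targets 27 in Golden Delicious and 16 in Granny Smith lay under the negative controls on all arrays compared, and 56 and 60 did so on all arrays of one side alone. Control and 1-MCP arrays were on different chips in both cultivars, so no comparison within a chip exists. In Golden Delicious all 3 controls were on use 3 of a chip, and the 1-MCP arrays on use 1 or 2. In Granny Smith the controls were on uses 1, 4 and 3 and the 1-MCP arrays on uses 1, 3 and 1. No fit took in the use of a chip, so its effect cannot be told apart from that of 1-MCP in Golden Delicious. With chip as a factor, estimated through the other groups, the counts were 73 in Golden Delicious and 105 in Granny Smith. The Golden Delicious count ran from 72 with chip and sector as factors to 309 in a fit of these groups alone, and was 131 with the replicate block. Without the failed array, which is in neither group, the counts were 207 and 185. Of the Golden Delicious calls 42.2% were higher, and 28.4% with cyclic loess, 32.1% with the median of spots, 21.2% with 2 arrays per group and 53.7% (166 higher and 143 lower) in the fit of these groups alone. In Granny Smith 50.4% were higher, and 61.3% with 2 arrays per group. With 3 against 3 arrays, 477 targets (43.3%) in Golden Delicious and 271 (24.6%) in Granny Smith showed no overlap between groups, where chance gives 10%.

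The comparison of control fruit after harvest with harvest fruit followed ripening off the tree. In both cultivars the control and harvest arrays were on different chips, so here too no comparison within a chip exists. In Golden Delicious 68 targets rose and 89 fell, with 28 and 46 at least 2-fold. In Granny Smith 33 rose and 49 fell, with 16 and 24 at least 2-fold. Of these, 18 rose in both cultivars (2.04 expected, Fisher's exact test, one-sided, p = 8.77e-15) and 21 fell in both (3.96 expected, p = 7.23e-12, Fisher's exact test), and 2 were called in opposite directions. With 2 arrays per group and no hybridisation or chip shared between the cultivars within a stage, 6 rose (0.458 expected) and 7 fell in both (0.981 expected). MDP0000326734 rose by 2.33 in Golden Delicious (limma adjusted p = 5.24e-13) and by 0.54 in Granny Smith (limma adjusted p = 0.0497) on the log2 scale. In Golden Delicious MDP0000205389 fell by 2.16 on the log2 scale and MDP0000240094 fell at least 1.32-fold (limma adjusted p = 1.10e-05 and 2.94e-05). The change differed between the cultivars for 43 targets, 25 more positive (58.1%) and 18 more negative in Golden Delicious. That balance depended on the scaling: 24 were more positive and 6 more negative with median scaling (80.0%), and 34 and 13 with cyclic loess (72.3%). The count was 24 with chip and sector as factors, 27 with the median of spots, 85 without the failed array, 110 without the 6 arrays that do not match the authors' columns and 149 in a fit of these groups alone.

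In Granny Smith all 3 harvest arrays were in sector 1 and all 3 control arrays in sector 2. With sector as a factor, which 6 breaker arrays alone inform, the count was 12, the called changes had a median ratio of 0.834 to those without it, and their standard errors grew 1.47 times. The Granny Smith count was also 33 without harvest 1, 50, 41 and 40 without control 1, 2 and 3, 46 with median scaling, 190 without the failed array, 242 without the 6 arrays that do not match the authors' columns, 234 with the authors' table and 178 in a fit of these groups alone. In Golden Delicious it was 402 in a fit of these groups alone and 247 without the failed array. With median scaling 61.7% of the Golden Delicious calls and 54.3% of the Granny Smith calls were higher, against 43.3% and 40.2%, and with cyclic loess 26.1% in Granny Smith.

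1-MCP fruit were also compared with harvest fruit. In Golden Delicious 65 targets were higher and 100 lower after 1-MCP, and in Granny Smith 45 were higher and 61 lower. Both cultivars shared 14 of the higher (2.66 expected) and 29 of the lower targets (5.54 expected), and 8 (1.17 expected) and 15 (1.93 expected) with 2 arrays per group and none on a hybridisation or chip shared within a stage. From harvest to 1-MCP fruit MDP0000326734 fell at least 2.19-fold in Golden Delicious and at least 3.38-fold in Granny Smith (limma adjusted p = 7.26e-20 and 6.89e-21). The share of higher targets in Golden Delicious was 39.4%, and 63.5% with median scaling and 27.5% with cyclic loess. In Granny Smith 42.5% were higher, and with sector as a factor the balance turned to 33 higher and 21 lower (61.1%), with chip and sector to 60.9% and with 2 arrays per group to 58.2%. The Granny Smith count thus fell to 54 with sector as a factor, and was 180 with hybridisation as a random block. All its harvest arrays were in sector 1 and all its 1-MCP arrays in sector 2. With sector the called changes had a median ratio of 0.945 to those without it and none changed sign, while standard errors grew 1.47 times.

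Sets of targets taken from one comparison were then followed in other arrays. The sets from breaker to harvest come from the fit without sector. The 46 targets that rose at least 2-fold from breaker to harvest had a mean of 11.59 ± 0.074 (log2, SD of 3 arrays) in control fruit and 10.62 ± 0.14 after 1-MCP in Golden Delicious, so that the set fell by 0.96. In Granny Smith the set fell by 0.93, from 11.53 ± 0.050 to 10.60 ± 0.22. Of the 46 targets 23 were called lower and 3 higher in Golden Delicious, and 25 lower and 1 higher in Granny Smith. These falls passed camera with an estimated correlation (adjusted p = 3.56e-04 and 7.02e-05) and did so with chip as a factor (adjusted p = 1.42e-03 and 2.11e-04). On the tree the set stood between 9.50 and 9.78 at every stage before harvest, and at 11.41 ± 0.082 and 11.47 ± 0.028 at harvest.

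The 60 targets that fell at least 2-fold from breaker to harvest had a set mean higher by 0.47 after 1-MCP in Golden Delicious, with 11 called higher and 2 lower, and by 1.02 in Granny Smith, with 23 called higher and 0 lower. Neither passed with an estimated correlation (adjusted p = 0.758 and 0.207), while fry gave 0.271 and 2.73e-03.

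**Figure D4:**
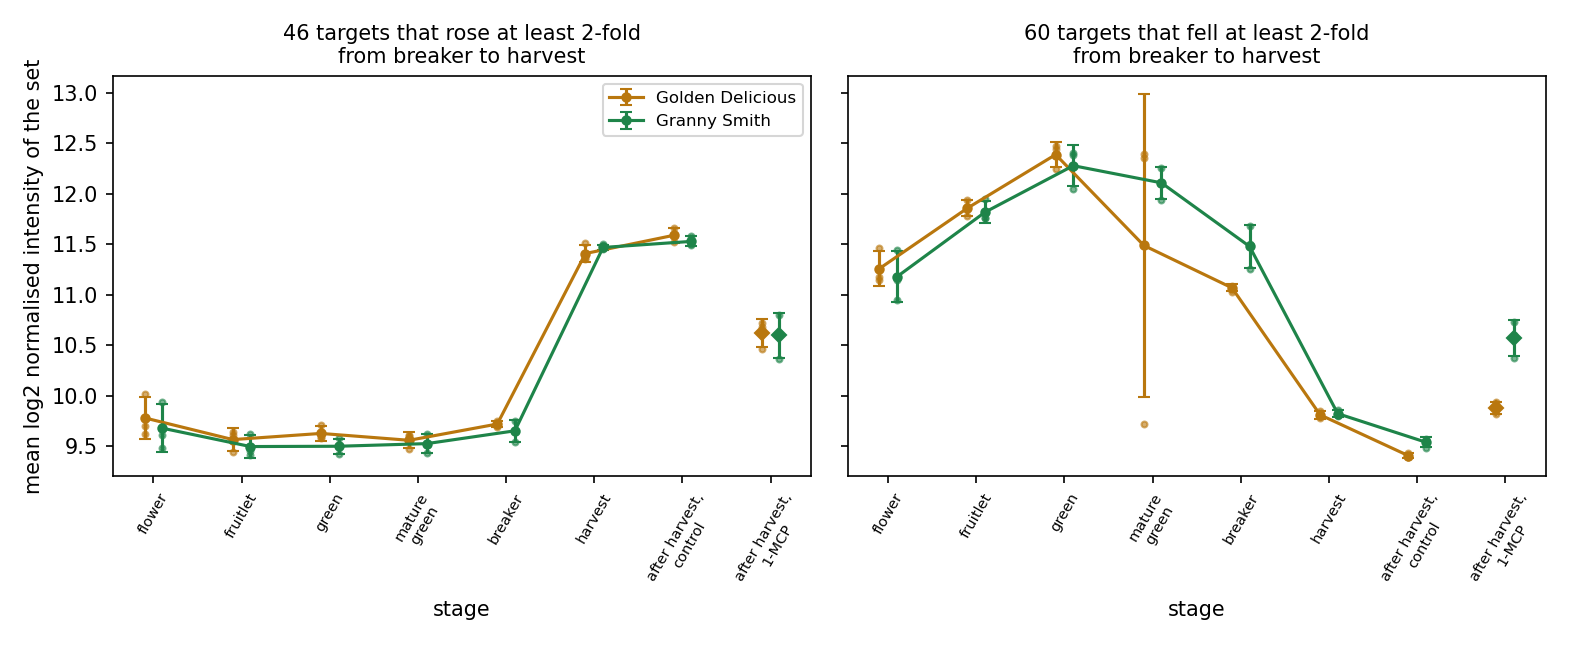
Mean log2 normalised intensity of the 46 targets that rose (left) and the 60 that fell (right) at least 2-fold from breaker to harvest, by stage and cultivar, with the SD of 3 arrays and each array as a dot. Diamonds are 1-MCP fruit, where the first set stands at 10.62 and 10.60 against 11.59 and 11.53 in the controls.

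Targets that changed after harvest in one cultivar were followed in the other. All Granny Smith harvest arrays were in sector 1 and its control and 1-MCP arrays in sector 2, and no set test took in sector. The 28 that rose at least 2-fold in Golden Delicious rose by a mean of 0.59 in Granny Smith (12 called higher, 1 lower) and fell by 1.22 there under 1-MCP (0 higher, 18 lower). The 16 that rose in Granny Smith rose by 1.33 in Golden Delicious (11 called higher, 0 lower) and fell by 0.91 under 1-MCP (2 higher, 6 lower). All 4 changes passed with an estimated correlation (adjusted p = 4.93e-03, 2.07e-05, 2.07e-05 and 3.82e-03). Within a cultivar the rise and the fall share the 3 control arrays, so they are not independent. From harvest to 1-MCP fruit the 28 fell by 0.63 in Granny Smith (adjusted p = 6.49e-03 with an estimated correlation). The 16 rose by 0.41 in Golden Delicious and did not pass (adjusted p = 0.647 with an estimated correlation). The 46 that fell after harvest in Golden Delicious fell by 0.70 in Granny Smith on average, and the 24 that fell in Granny Smith fell by 0.77 in Golden Delicious. These 2 passed camera with a preset correlation and not with an estimated one (adjusted p = 0.161 and 0.207 with an estimated correlation). In each of these sets the arrays of the groups did not overlap, and the exact permutation test gave p = 0.1, the smallest it allows. In the fit with 2 arrays per group and no hybridisation or chip shared between the cultivars within a stage, the sets were chosen anew. They held 25 and 10 targets that rose and 39 and 15 that fell in Golden Delicious and Granny Smith. The sets that rose in one cultivar rose in the other (by 0.60 and 1.24) and fell under 1-MCP there (by 1.25 and 0.94). All 4 of these changes passed with an estimated correlation (adjusted p of at most 9.94e-04). The sets that fell did not pass in the other cultivar (adjusted p = 0.0930 and 0.117 with an estimated correlation).

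On the tree the comparisons of successive stages used the mean of both cultivars, 6 arrays per side. From flower to fruitlet 281 targets rose and 203 fell, of which 104 and 73 changed at least 2-fold. From fruitlet to green fruit 189 rose and 174 fell (46 and 48 at least 2-fold). From green to mature green 49 rose and 175 fell (3 and 53), and from mature green to breaker 118 rose and 128 fell (11 and 41). From breaker to harvest 173 rose and 211 fell (46 and 60). From breaker, where it lay under the negative controls on all arrays, MDP0000326734 rose to harvest (limma adjusted p = 1.08e-25; no fold is given), and MDP0000205389 rose by 2.22 on the log2 scale (limma adjusted p = 1.59e-09).

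**Figure D5:**
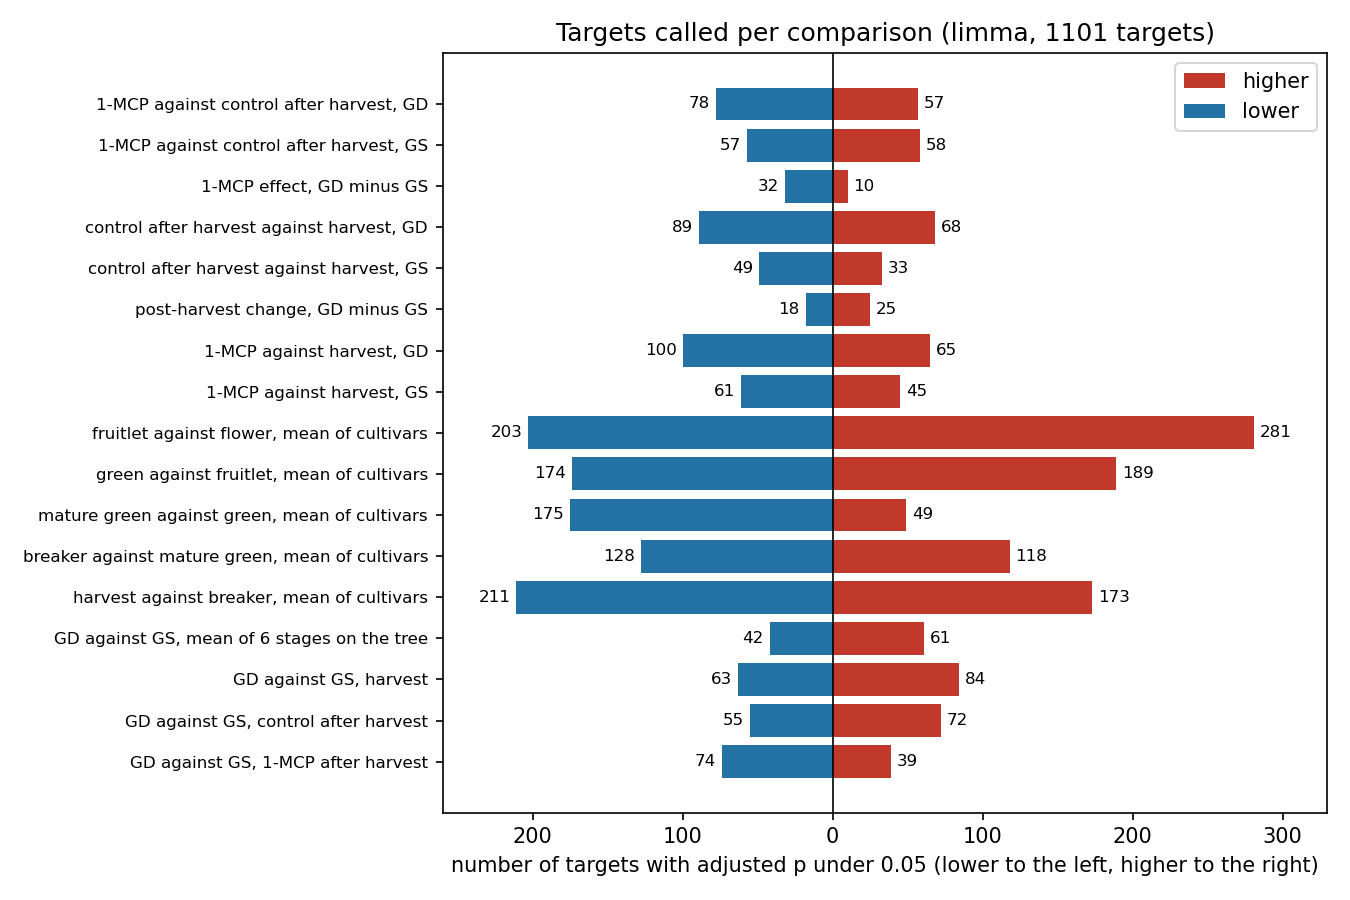
Number of targets called (adjusted p under 0.05, limma, 1101 targets) in each of 17 comparisons, higher to the right and lower to the left of 0. From flower to fruitlet 281 rose and 203 fell, and under 1-MCP 57 rose and 78 fell in Golden Delicious and 58 rose and 57 fell in Granny Smith.

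The 2 comparisons with mature green fruit hold the failed array and their counts were 87 and 86 in fits of their groups alone. Without the 6 arrays that do not match the authors' columns 58.6% of the targets called from green to mature green were higher, against 21.9%. The arrays of the 2 cultivars share hybridisations, which this fit ignores. With hybridisation as a random block 191 targets were called from fruitlet to green, 74 higher and 117 lower, against 363. At breaker 4 of 6 arrays were in sector 2 and at harvest all 6 in sector 1. With sector as a factor the count from breaker to harvest was 218, and 195 with chip and sector, against 384. With sector the called changes had a median ratio of 1 to those without it and none changed sign, while standard errors grew 1.43 times. The share of higher targets also depended on the scaling: from fruitlet to green it was 52.1%, and 41.1% with median scaling. From mature green to breaker it was 48.0%, and 24.2% with cyclic loess. From breaker to harvest it was 45.1%, and 28.8% with median scaling and 55.2% with cyclic loess.

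The cultivars differed in their course over the 6 stages on the tree for 253 targets (moderated F test), and over the 4 stages other than green and mature green for 282. The fit over 4 stages also leaves out the failed array, without which the 6 stages gave 339. Averaged over the 6 stages 61 targets were higher and 42 lower in Golden Delicious, with 1 and 1 at least 2-fold. At harvest 84 were higher and 63 lower in Golden Delicious, of which 41 and 38 at least 2-fold. In control fruit after harvest 72 were higher and 55 lower, and in 1-MCP fruit 39 were higher and 74 lower. Golden Delicious took 22 of its 24 arrays from sector 1 and Granny Smith 20 of its 24 from sector 2. With sector as a factor the mean over stages gave 3 targets, and the control and 1-MCP fruit gave 57 and 72. The called changes had a median ratio of 0.981, 0.984 and 1.05 to those without the factor, and 2 changed sign in the mean over stages. The log2 differences of all targets with and without it correlated at r of 0.750, 0.932 and 0.947, and standard errors grew 2.02, 1.47 and 1.47 times. At harvest both cultivars were in sector 1, and the count with sector as a factor was 148. With hybridisation as a random block, which takes in the likeness of arrays in one hybridisation, the course over stages gave 409, the mean over stages 251, and control and 1-MCP fruit 216 and 207. Without the failed array the counts at harvest, in control and in 1-MCP fruit were 244, 210 and 180. The mean over stages gave 181 without Golden Delicious mature green 3, 269 without the green and mature green fruit and 54 with median scaling, and its share of higher targets was 59.2%, against 70.4% with median scaling and 71.6% with cyclic loess. In 1-MCP fruit that share was 34.5%, and 24.1% with cyclic loess.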

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

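The splits of the arrays, the fits with chip, without the failed array and with sector, the reading of the fit without 1 array as a test of it, and the score of the green arrays were tests chosen after the results were seen. The permutation of residuals and the F test over 4 stages were set down before their values were seen.

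The effect of 1-MCP differed between Golden Delicious and Granny Smith for 42 targets in the test of the difference itself. Treated and control arrays were on different chips, but with chip as a factor 43 targets passed, which argues against a constant shift of each chip as the whole cause. That factor does not take in the single hybridisation, which control and 1-MCP arrays never share. Nor does it take in how often a chip had been used, which differed between control and 1-MCP arrays of Golden Delicious. Of the 6 arrays that do not match the authors' columns 1 is compared here (Granny Smith 1-MCP 2), and without it 38 passed, which argues against that array as the whole cause. The count rose to 84 without the failed array, which is in no group compared and enters through the pooled variance. Of 100 splits of the 12 arrays 10 gave as many targets, with up to 96 in others, since exchanging cultivar labels moves the difference between cultivars into this test. When the means of cultivar and treatment were kept and residuals were permuted, 1 of 100 draws gave as many, the real one included, with at most 11 in the others, so chance is excluded only in that form, which treats arrays as independent, and not by the splits. A difference between the cultivars in their response to blocked ethylene perception may remain, as a hypothesis found on these arrays and not tested on others.

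The course over the 6 stages on the tree differed between the cultivars for 253 targets. Some green and mature green arrays are of doubtful cultivar, and 282 targets passed over the other 4 stages. A difference in course is thus called without those arrays. The 2 counts cannot be compared, since the fit over 4 stages also leaves out the failed array. Without that array alone the test over 6 stages gave 339. Cultivar and sector nearly coincide, but no target was called for the sector term by limma and 1.09% (12 of 1101) had an unadjusted p under 0.05 for it, fewer than chance gives, with a test that rests on 6 breaker arrays. Of 100 splits 1, the real one, gave as many targets, and the others gave up to 187. Of 100 splits that part the 2 arrays of each hybridisation, as the real one does, 1 gave as many, with up to 184 in the others, so chance is excluded in both forms. With sector as a factor 178 targets passed, and a difference in development between the cultivars may account for these as an untested hypothesis.

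The change after harvest differed between the cultivars for 43 targets in the test of the difference. As many came from 10 of 100 splits (up to 106 in others), and from 1 of 100 draws of permuted residuals, the real one included (up to 7 in others). With sector and chip as factors 24 targets passed, and 85 without the failed array, 110 without the 6 arrays that do not match the authors' columns and 149 in a fit of these groups alone.

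In one hybridisation 2 green arrays stood with the other cultivar. A cultivar score (the mean of 29 targets higher in Golden Delicious minus the mean of 35 higher in Granny Smith, chosen without the green stage) was -1.50 for Golden Delicious green 3 and -0.38 for Granny Smith green 1. The other Golden Delicious green arrays scored -0.59 and -0.38 and the other Granny Smith green arrays -1.44 and -1.44. The Golden Delicious array thus scored -1.12 relative to its Granny Smith partner, where the other green arrays differ by 0.958 the other way, as an exchange of 2 samples between the sectors or labels of that hybridisation would give. The score does not decide whether that exchange took place. The 0.958 rests on Golden Delicious green 2 and Granny Smith green 3 as placed here, and the authors' columns match their sectors exchanged. If the scores of these 2 were exchanged, the other green arrays would no longer part by cultivar. A score built in the same way, with targets chosen without the mature green stage and with the green arrays, reversed the cultivars at mature green. It put all 3 Golden Delicious arrays (-1.43, -1.40 and -1.22) under all 3 Granny Smith arrays (-0.08, -0.02 and 0.00). At flower, fruitlet, breaker and harvest, each scored with targets chosen without that stage, the order was the other way. A mislabelled sample thus stays open. Both authors' columns match sector 2, the Granny Smith array's, as an exchange predicts for the Golden Delicious column alone, at r of 0.911 for the Golden Delicious column (0.607 with sector 1) and 0.924 for the Granny Smith column (0.593 with sector 1). These 2 columns correlate at 0.929, and all these r are on ranks with each target's mean rank taken off. The samples were kept as labelled, and with the 2 sectors exchanged the cultivar by stage test gave 305 targets. No biological explanation was tested.

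With 3 against 3 arrays there are 10 splits, too few for a share under 0.05, and the real split alone gave its count in each case (1 of 10). For 1-MCP against control the real counts were 135 and 115 and the highest other 0 in both cultivars. For control against harvest they were 157 and 82, with 0 and 1 in other splits. For 1-MCP against harvest they were 165 and 106, with 0 and 63. Between the cultivars they were 147 at harvest, 127 in control and 113 in 1-MCP fruit, with 2, 0 and 6. In the Golden Delicious comparisons after harvest the residuals of arrays with the same replicate number correlated above 0.1. If these numbers are read as pairs, the other splits that part as many pairs as the real one also gave 0.

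For the successive stages 100 splits were drawn, the real one included, with arrays treated as independent. Flower to fruitlet was reached by 1 split (484, highest other 327), fruitlet to green by 1 (363, highest other 225) and breaker to harvest by 1 (384, highest other 148). Green to mature green was reached by 4 (224, highest other 257) and mature green to breaker by 2 (246, highest other 272). Arrays of one hybridisation resemble each other, so the splits that keep the arrays of a hybridisation together were counted as well. From breaker to harvest 1 of 52 such splits gave as many (384, highest other 167), so chance is excluded. From green to mature green 3 of 28 did (224, highest other 252) and from mature green to breaker 2 of 28 (246, highest other 294), so chance is not excluded for these 2. For flower to fruitlet (484, highest other 98) and fruitlet to green (363, highest other 0) there are 10 such splits, too few for a share under 0.05, and 1 of 10 gave as many.

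The difference of cultivars averaged over 6 stages was reached by 1 of 100 splits (103, highest other 90), and by 1 of 100 that part the 2 arrays of each hybridisation as the real one does (highest other 92), so chance is excluded in both forms. Cultivar and sector nearly coincide in the real split, and the other splits break this up. They therefore cannot tell cultivar from sector. With sector as a factor 3 targets passed, with standard errors 2.02 times as large.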

How the results depend on the processing

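The fits with chip as a fixed factor, hybridisation or sector, those without the 6 arrays, the failed array or 2 stages, the fit with 2 arrays per group, the other sectors for green arrays and the fit of all targets were tests chosen after the data were seen. No count had a target called both ways in opposite directions, except 1 target with the median of spots, and the 36 single-target values of the ranking kept direction and threshold in 920 of 924 alternatives and direction in the other 4. Counts stayed within 1.5 times, for each of the 18 comparisons, with cyclic loess, no background correction, the 25th percentile filter, the replicate block, the variance trend, chip as a random block and both reassignments of the green sectors. The narrow signal over background limits what can be tested, and the set tests planned for gene lists, with their alternatives, were not run because no list matched. Scaling moved the median change of all tested targets by up to 0.13. For 1-MCP against harvest in Golden Delicious it was 0.04, 0.15 with median scaling and -0.07 with cyclic loess. With cyclic loess it went from -0.01 to -0.13 for control against harvest in Granny Smith, from 0.02 to -0.11 for the 1-MCP effect between cultivars, from -0.04 to 0.07 for the post-harvest change between cultivars, from 0.05 to -0.05 for the cultivars in 1-MCP fruit and from 0.06 to -0.06 for mature green to breaker.

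Outside that range the counts were as follows, and the cause was not tested unless given. Median scaling gave 46 for control against harvest in Granny Smith and 54 for the cultivars over 6 stages. The median of spots gave 27 for the post-harvest difference and 66 for the cultivars over 6 stages. A fit of the groups compared alone gave 309 for 1-MCP against control in Golden Delicious, 78 for the 1-MCP effect between cultivars, 402 and 178 for control against harvest in Golden Delicious and Granny Smith, 149 for the post-harvest difference, 397 for 1-MCP against harvest in Golden Delicious, 87 for green to mature green, 86 for mature green to breaker, and 250 and 289 between cultivars at harvest and in control fruit. The authors' table, with more targets tested, gave 250 and 181 for 1-MCP against control, 65 for its difference, 285 and 234 for control against harvest, 71 for its difference, 306 and 278 for 1-MCP against harvest, 929, 625, 618 and 905 for flower to fruitlet, fruitlet to green, mature green to breaker and breaker to harvest, and 239 and 192 between cultivars at harvest and in control fruit. All targets of the array gave 130 for control against harvest in Granny Smith, 754 for flower to fruitlet, 445 for mature green to breaker and 662 for breaker to harvest.

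Chip as a fixed factor gave 73 for 1-MCP against control in Golden Delicious. Hybridisation as a random block gave 83 for the 1-MCP effect between cultivars, 180 for 1-MCP against harvest in Granny Smith, 191 for fruitlet to green, 409 for cultivar by stage, and 251, 216 and 207 between cultivars over 6 stages, in control and in 1-MCP fruit. Sector as a factor gave 12 for control against harvest and 54 for 1-MCP against harvest in Granny Smith, 218 for breaker to harvest, and 3, 57 and 72 between cultivars over 6 stages, in control and in 1-MCP fruit, where standard errors grew 1.43 to 2.02 times. Chip and sector together gave 72 for 1-MCP against control in Golden Delicious, 13 and 64 for control and 1-MCP against harvest in Granny Smith, 24 for the post-harvest difference, 195 for breaker to harvest, and 3, 57 and 71 between cultivars over 6 stages, in control and in 1-MCP fruit.

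Without the 6 arrays the counts were 252 and 187 for 1-MCP against control, 90 for its difference, 285 and 242 for control against harvest, 110 for its difference, 322 and 287 for 1-MCP against harvest, 381 for mature green to breaker, 384 for cultivar by stage, and 156, 267 and 231 between cultivars over 6 stages, at harvest and in control fruit. Without the failed array they were 207 and 185 for 1-MCP against control, 84 for its difference, 247 and 190 for control against harvest, 85 for its difference, 277 and 176 for 1-MCP against harvest, and 244, 210 and 180 between cultivars at harvest, in control and in 1-MCP fruit. Without green and mature green fruit the cultivars differed over 4 stages for 269 targets. With 2 arrays per group, so that the cultivars shared no hybridisation or chip within a stage, the counts were 85 and 75 for 1-MCP against control, 90 and 34 for control against harvest, 23 for its difference, and 109 and 67 for 1-MCP against harvest.

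The share of higher targets moved by over 10 points in some fits, beyond those given with the results. It was 12.9% with the median of spots for the 1-MCP effect between cultivars (23.8%), 46.4% with hybridisation as a random block for the cultivars in 1-MCP fruit (34.5%), and 69.4% with the authors' table and 33.3% with sector for the cultivars over 6 stages (59.2%). It was 69.6% with 2 arrays per group for the post-harvest difference (58.1%), 37.8% without the 6 arrays for mature green to breaker (48.0%) and 38.7% with hybridisation as a random block for fruitlet to green (52.1%). For green to mature green it was 9.20% in a fit of the groups alone and 45.1% with the authors' table (21.9%).

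Leaving out 1 array of the groups compared at a time (the failed array, outside most of them, moved counts further, as given above) gave 100 to 121 and 87 to 110 for 1-MCP against control in Golden Delicious and Granny Smith, 34 to 45 for its difference, 113 to 128 for control against harvest in Golden Delicious and 35 to 43 for the post-harvest difference. In Granny Smith control against harvest gave 33 (without harvest 1) to 68, and 50, 41 and 40 without control 1, 2 and 3. 1-MCP against harvest gave 114 to 153 and 77 to 148. The stages in order gave 442 to 495, 303 to 386, 193 to 297, 196 to 330 and 337 to 373, and cultivar by stage 220 to 339. Between cultivars the ranges were 88 to 181 over 6 stages (181 without Golden Delicious mature green 3), 125 to 142 at harvest, 99 to 108 in control and 89 to 137 in 1-MCP fruit.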

Other observations

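The test of carry-over was set down before its value was seen, and the sets, the peak stages and the peak stages without the failed array were chosen after the data were seen.

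Of the tested targets 824 were called in at least 1 comparison of successive stages on the tree, and for each the stage with the highest mean was taken. In 523 (63.5%) it was the same stage in both cultivars. The choice of targets by the mean of both cultivars favours such agreement, and the cultivars share hybridisations, so no expected share is given. In Golden Delicious 178 targets were highest in flower, 149 in fruitlet, 136 in green fruit, 61 in mature green fruit, 120 at breaker and 180 at harvest. In Granny Smith the numbers were 176, 149, 107, 109, 96 and 187. At mature green 14 targets were highest in both. Without the failed array, Golden Delicious mature green 3, the numbers in Golden Delicious became 175, 139, 85, 161, 86 and 178, and 55 targets were highest at mature green in both cultivars, while 63.6% had the same stage in both.

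The 43 targets that fell at least 2-fold under 1-MCP in Golden Delicious fell by a mean of 1.23 under 1-MCP in Granny Smith, with 25 called lower and 0 higher (adjusted p = 2.84e-05 with an estimated correlation). The 28 that fell in Granny Smith fell by 1.96 in Golden Delicious, with 19 called lower and 0 higher (adjusted p = 5.94e-09 with an estimated correlation). Of the 21 that rose in Golden Delicious 9 were called higher and 0 lower in Granny Smith, with a mean change of 1.12 (adjusted p = 2.02e-02 with an estimated correlation). Of the 41 that rose in Granny Smith 14 were called higher and 0 lower in Golden Delicious, with a mean change of 0.66 that did not pass (adjusted p = 0.341 with an estimated correlation). The 41 targets that fell at least 2-fold from mature green to breaker had a set mean higher by 0.99 after 1-MCP in Granny Smith, with 19 called higher and 1 lower, which did not pass (adjusted p = 0.105 with an estimated correlation). Sets from earlier stages on the tree gave no call with an estimated correlation.

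With targets chosen without the mature green stage, the cultivar score of its arrays lay at -1.43, -1.40 and -1.22 in Golden Delicious. In Granny Smith it lay at -0.08, -0.02 and 0.00. This is the reverse of the order at the flower, fruitlet, breaker and harvest stages, each scored likewise. The headers put Golden Delicious green 2 and Granny Smith green 3 in the sectors used here. The score goes with that placement but does not decide it, given its reverse at mature green. The authors' columns match these sectors exchanged, at r (on centred ranks) of 0.966 and 0.958 against 0.625 and 0.617. Golden Delicious green 3 is the other array whose authors' column is closer to the other sector (0.911 against 0.607).

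Chips were used up to 4 times, and signal left from an earlier sample could pull an array toward it. For 32 arrays the earlier sample was known. An array's deviation from its group mean was correlated with the difference of the earlier sample's group. The mean r was -0.011, with 14 of 32 above 0 (one-sided permutation p = 0.32), so no pull that differed between replicates was seen. A pull shared by the replicates of a group is taken off with the group mean, so the test cannot exclude it. Golden Delicious controls 1 and 2, for example, both followed Golden Delicious fruitlet arrays.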
